A study of Mus musculus with 4 samples.

How the data were processed

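Monocytes with intermediate CD11b and low F4/80 were sorted by flow cytometry from the livers of adult C57BL/6 mice and stimulated for 2 days, per the labels' protocols. RNA was then taken up in Trizol, and TruSeq libraries were made from total RNA. The series held 4 libraries in 2 groups, IgG and OX40 Fc, with 2 libraries in each. Libraries were assigned to groups by their titles. The title of OX40 Fc replicate 2 names OX40, while its description names OX41 Fc; the title was followed, and the protocol names no OX41.

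The deposited values were RPKM, a read count scaled by exon length and library size, in 1 table of 22201 genes with an Ensembl identifier each, and 0 of these genes were at 0 in all 4 libraries. The submitters' processing notes list Bowtie 0.12.2 and the build mm8, without saying what each was used for. The counting tool, the annotation and any filter are not given in the sources used here. Of the identifiers, 22109 matched the mouse GRCm38 annotation (GENCODE M21), which gave symbols, positions and merged exon lengths, and 92 did not. That annotation is later than mm8. The deposited RPKM multiplied by its merged exon length came out within 0.02 of a whole multiple of 1 step per library for 82.5% to 83.4% of values below 500 steps, where chance gives 4%. All coordinates are those of GRCm38.

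The step gives the number of reads that the RPKM scale was divided by: 23193354, 25443260, 22687302 and 33700789 for IgG replicates 1 and 2 and OX40 Fc replicates 1 and 2. The reads recovered over all genes with a length summed to 33037133, 31937367, 26595878 and 38558075, above these figures, so the figures stand for the scale of each library and not for its sequenced total. The ferritin gene Fth1 took 15.3%, 11.5%, 10.4% and 9.58% of the recovered reads. Summed RPKM was 505013, 421648, 414345 and 330460. At the median length of 3140 bases, 1 RPKM stood for 73, 80, 71 and 106 reads.

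The comparison was OX40 Fc against IgG over all 4 libraries with no covariate. Values were taken as log2(RPKM + 1), genes at or above 1 RPKM in at least 2 libraries were kept (10885), and limma 3.58.1 was run in R 4.3.3 with a mean-variance trend. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The fit had 2 residual and 2.9 prior degrees of freedom. The test for counts that the design also held was not needed, since the values were RPKM.

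Gene lists were fixed before the data were examined, 33 in all, and 32 had at least 5 tested members. They covered macrophage activation, immune and metabolic pathways, stress responses and markers of other cell types in liver. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma, adjusted by Benjamini-Hochberg over the lists. Members were also counted when adjusted over the list alone; these counts are not corrected across the 33 lists, and lists share members.

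Named genes followed a rule fixed before the data were examined. It took 12 genes per direction with a mean of at least 5 RPKM whose OX40 Fc values both lay on 1 side of both IgG values, ordered by unadjusted p where none passed, without clone-like names. Of these, 1 gene is not reported here. It also took the 2 list members with the smallest p where none passed, and always Tnfsf4 and Tnfrsf4. Other genes named as list members passed when adjusted over the list alone, apart from H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Adgre1, which did not. S100a8, S100a9, Lta, H2-M2 and single immunoglobulin and marker genes were singled out after their values were seen.

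Alternatives fixed beforehand were a replicate block, each library left out in turn, no filter, a filter of 5 RPKM, a pseudocount of 0.1, trimmed mean scaling, quantile normalization, no variance trend and other thresholds. Added after the data were seen were a length correction, the same with a replicate block or without OX40 Fc replicate 2, and limma-voom on the implied reads. The length correction subtracted a loess curve (span 0.3, degree 1) of each library's deviation from the gene mean against log2 length, over 10865 genes with a length. Members of the immunoglobulin, Bcl2a1 and Serpina1 families are near-identical copies and their values are uncertain. Exons of Lox, Il1a, Pltp, Folr2 and Ctsl overlap annotated genes on the other strand (for Pltp, Ctsa), and whether counting used strand is not given in the sources used here, so reads of these partners cannot be told apart.

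The procedure was tested on simulated data of this design in 10 draws with 200 changed genes of 10865. It recovered 0.1% of genes changed 2-fold, 39.3% of those changed 4-fold and 65% of those changed 8-fold, with 2.3 false calls among 71.8 calls per draw. Lists of 30 genes moved by a log2 of 1 had an unadjusted camera p under 0.05 in 10 of 10 draws, and unmoved lists in 0. The simulated noise was independent between genes and libraries and had no length trend, unlike these data. The simulation therefore cannot show how often the list test calls falsely here. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.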

Results

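Messenger RNA was sequenced from mouse hepatic monocytes, sorted from the livers of adult C57BL/6 animals as cells with intermediate CD11b and low F4/80. The sorted cells were cultured for 2 days with control IgG or with OX40 Fc, a protein in which the OX40 receptor is joined to an antibody Fc part, at a stated concentration of 2 ug/ml. Each of the 2 groups had 2 libraries. The values were RPKM for 22201 genes. The spacing of the values placed 23193354 and 25443260 reads behind the scale of the IgG libraries, and 22687302 and 33700789 reads behind that of OX40 Fc replicates 1 and 2. At the median gene length of 3140 bases, 1 RPKM then stood for 71 to 106 reads. The comparison asked which transcripts differed between monocytes given OX40 Fc, which binds the OX40 ligand, and monocytes given IgG. The labels did not say whether the duplicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

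No single gene passed the test over all genes. Among genes higher in both OX40 Fc libraries, those with the smallest p included the cytokine genes Il12a, Csf3 and Il1a and the chemokine genes Ccl3 and Cxcl2, beside Lcn2, Lox and others. Il12a, which encodes the p35 subunit of interleukin-12, averaged 0.174 ± 0.211 RPKM with IgG and 15.1 ± 3.55 RPKM with OX40 Fc (SD, n = 2 in each group). Lcn2, encoding the siderophore-binding protein lipocalin-2, averaged 4.03 ± 0.84 and 114 ± 44.5 RPKM. Csf3, encoding granulocyte colony-stimulating factor, averaged 6.28 ± 2.06 and 81.9 ± 6.45 RPKM. Lox, encoding the collagen cross-linking enzyme lysyl oxidase, averaged 2.81 ± 0.166 and 19.4 ± 1.05 RPKM.

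On the log2(RPKM + 1) scale, which understates the change of low genes, the log2 fold change was 3.77 (SE 0.26) for Il12a, 4.47 (SE 0.34) for Lcn2, 3.54 (SE 0.27) for Csf3 and 2.42 (SE 0.19) for Lox. For each of these 4 genes the limma adjusted p (Benjamini-Hochberg) was 0.091. Mir7678, a microRNA gene of 71 bases, had the same adjusted p in limma with Benjamini-Hochberg adjustment, 0.091, at a log2 fold change of 3.64, on 2 and 3 reads in the IgG libraries. It lies inside Slpi, a protease inhibitor gene on the same strand at 157 ± 16.7 and 491 ± 198 RPKM, so its reads cannot be separated from those of Slpi and its value is uncertain. Ccl3 and Cxcl2, encoding chemokines that attract leukocytes, averaged 66.9 ± 14.9 and 36.6 ± 6.98 RPKM with IgG, against 646 ± 30 and 347 ± 64 RPKM with OX40 Fc. The log2 fold change was 3.27 for Ccl3, 3.21 for Cxcl2 and 3.04 for Hcar2, a niacin and ketone body receptor gene, each with a limma Benjamini-Hochberg adjusted p of 0.11. Il1a, encoding interleukin-1 alpha, averaged 14.8 ± 0.656 and 207 ± 84.5 RPKM. Mir155hg, the host transcript of microRNA 155, averaged 1.12 ± 0.114 and 13.6 ± 4.2 RPKM, and Cst7, encoding cystatin F, 5.44 ± 0.0317 and 24.2 ± 1.91 RPKM. The limma Benjamini-Hochberg adjusted p was 0.13 for Il1a, Mir155hg and Cst7, and 0.14 for Siglece, a sialic acid receptor at 8.41 ± 1.64 and 41 ± 0.666 RPKM.

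Among genes lower in both OX40 Fc libraries, none of which passed over all genes, those with the smallest p included Pltp, Entpd1, Pparg and Apoe. Pltp, encoding phospholipid transfer protein, averaged 15.5 ± 1.35 RPKM with IgG and 2.48 ± 0.342 RPKM with OX40 Fc (SD, n = 2 in each group). Pparg, a lipid-sensing nuclear receptor, averaged 19.6 ± 1.7 and 5.56 ± 0.427 RPKM, and Apoe, encoding apolipoprotein E, 855 ± 33.6 and 226 ± 11.4 RPKM. Entpd1, the ectonucleotidase CD39, averaged 11.5 ± 1.31 and 2.62 ± 0.405 RPKM, and Igf1, encoding insulin-like growth factor 1, 34.5 ± 13.6 and 7.73 ± 0.589 RPKM. The Fc gamma receptor gene Fcgr4 averaged 59.4 ± 4.03 and 23.8 ± 1.68 RPKM. The log2 fold change was -2.25 (SE 0.2) for Pltp, -1.79 for Entpd1, -1.65 for Pparg, -1.91 for Apoe, -1.97 for Igf1 and -1.29 for Fcgr4. Sirpb1c had -1.58, Fabp7, a fatty acid-binding protein gene, -2.58, P2ry6, a nucleotide receptor gene, -1.51, Anxa1, encoding annexin A1, -1.6, and the platelet chemokine gene Ppbp -3.08. The limma Benjamini-Hochberg adjusted p was 0.11 for Pltp, and 0.21 to 0.3 for the other 10 of these genes.

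**Figure D1:**
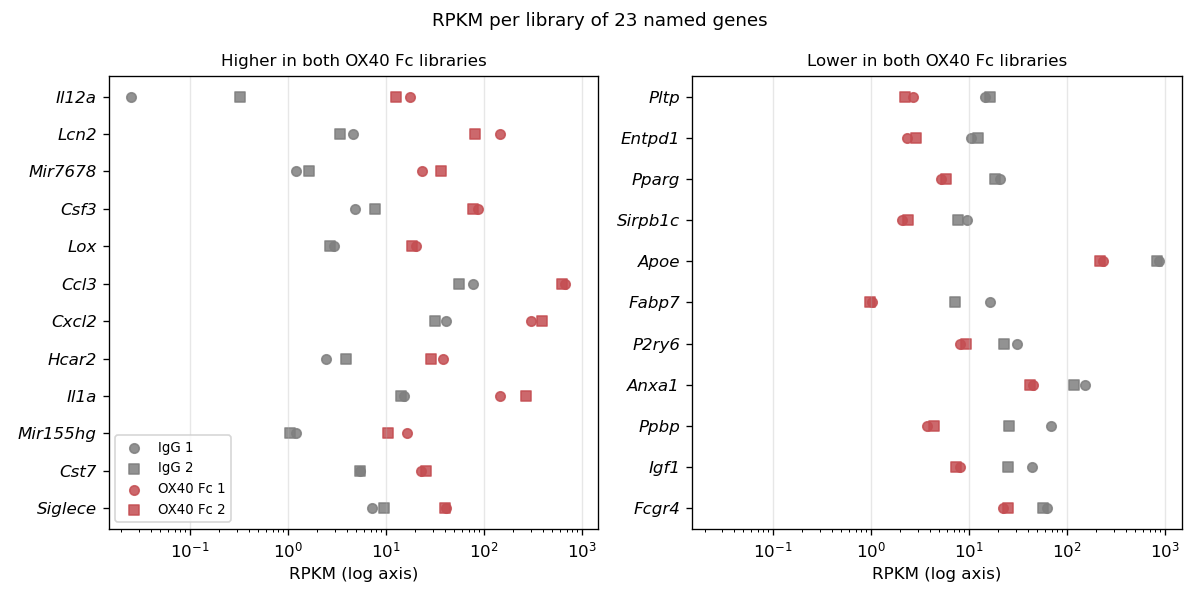
RPKM of 23 named genes in each library on a log axis, with IgG in grey and OX40 Fc in red, circles for replicate 1 and squares for replicate 2. In the left panel both OX40 Fc points of each of the 12 genes lie above both IgG points, for Csf3 at a mean of 81.9 against 6.28 RPKM; in the right panel both lie below, for Pltp at 2.48 against 15.5 RPKM. The genes were picked for that separation.

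In the mouse GRCm38 annotation (GENCODE M21), Il12a (ENSMUSG00000027776) lies on chromosome 3 from 68690644 to 68698547 on the plus strand, and Lcn2 (ENSMUSG00000026822) on chromosome 2 from 32384633 to 32388252 on the minus strand. Csf3 (ENSMUSG00000038067) lies on chromosome 11 from 98701263 to 98703629, and Lox (ENSMUSG00000024529) on chromosome 18 from 52516067 to 52529867. Pltp (ENSMUSG00000017754) lies on chromosome 2 from 164839518 to 164857711. All 5 are protein-coding genes, and each value covers the merged exons of its gene.

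Of 10885 genes tested with limma, 0 were higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05, and limma-voom on the implied reads also gave 0 and 0. At an unadjusted p under 0.05 limma gave 877 genes, 456 higher and 421 lower, where 544 would fall by chance. That excess was absent when either IgG library was left out, in fits with fewer libraries. In 2051 genes both OX40 Fc values lay above both IgG values and in 2554 both lay below, where chance places 16.7% of genes in each class. The counts differed with the OX40 Fc library used. Without OX40 Fc replicate 2, limma gave 120 higher and 93 lower genes, and without OX40 Fc replicate 1 it gave 465 and 1258, with the lone library assumed to vary like the IgG libraries. Of these 213 and 1723 genes 136 were called in both fits, 8 of them in opposite directions; the fits share the IgG libraries, so genes called in both are not independent evidence. In simulated data of this design, 39.3% of genes changed 4-fold and 0.1% of those changed 2-fold were recovered. The simulated noise was independent between genes and had no length trend, so these shares may not hold for these data.

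OX40 Fc replicate 2 differed from the other 3 libraries along gene length. Its log2 difference from the IgG mean increased by 0.26 (SE 0.005) for each doubling of gene length over 10865 genes, against -0.03 (SE 0.0035) in OX40 Fc replicate 1 and -0.06 (SE 0.0024) between the IgG replicates. Among the 1359 shortest genes, of at most 1422 bases, the median deviation from the gene's mean was -0.64 in OX40 Fc replicate 2, and 0.34, 0.19 and 0.25 in IgG replicates 1 and 2 and OX40 Fc replicate 1. The first principal component held 67.1% of the variance and placed OX40 Fc replicate 2 at 56.3, away from -30.4, -16.1 and -9.7 for the same other 3 libraries. When each library's trend with length was removed, a step chosen after the data were seen, limma gave 17 higher genes and 1 lower at a Benjamini-Hochberg adjusted p under 0.05. The higher genes were H2-M2, Tnf, Lta, Lox, Lcn2, Il12a, Csf3, Hcar2, Cxcl2, Mir155hg and 7 immunoglobulin genes, and the lower one was Pltp. In that fit Tnf, the tumour necrosis factor gene at 36.8 ± 3.82 and 242 ± 56.2 RPKM, had a log2 fold change of 2.94 (SE 0.23, limma Benjamini-Hochberg adjusted p = 0.03). Of the immunoglobulin genes, Ighg2b and Iglc2 are constant region genes and the others variable segments. The variable segments rested on 0 or 1 reads in each IgG library and on 17 to 55 in each OX40 Fc library. The length correction also shifted values at or near 0 RPKM, so the calls of these segments depend on it. Immunoglobulin genes have closely similar copies whose reads may be split between them, so their values are uncertain.

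**Figure D2:**
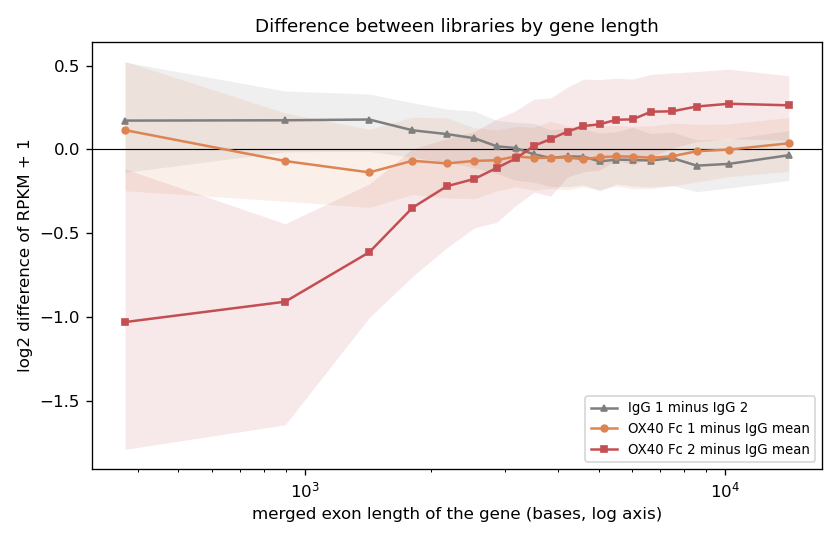
Median log2 difference of RPKM + 1 between libraries (vertical axis) by merged exon length in bases on a log axis, with the range between quartiles shaded. OX40 Fc replicate 2 against the IgG mean climbs with length at a slope of 0.26 per doubling, while OX40 Fc replicate 1 against the IgG mean (-0.03) and IgG replicate 1 minus replicate 2 (-0.06) stay nearer 0.

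Genes of classical, M1-type macrophage activation were higher as a group with OX40 Fc. Of the 25 members tested, 20 lay higher in both OX40 Fc libraries than in both IgG libraries, with a median log2 fold change of 1.78. Acod1, the itaconate-producing enzyme of activated macrophages, averaged 44.3 ± 9.17 RPKM with IgG and 353 ± 121 RPKM with OX40 Fc. Il1b, encoding interleukin-1 beta, averaged 31.3 ± 9.01 and 265 ± 144 RPKM, Il6 3.07 ± 0.081 and 22.7 ± 12.9 RPKM, and Nos2, the inducible nitric oxide synthase, 0.741 ± 0.00235 and 6.87 ± 3.22 RPKM. Targets of the inflammatory transcription factor NF-kB were also higher as a group, with 30 of 35 members higher in both OX40 Fc libraries and a median log2 fold change of 0.72. Among them Sod2, encoding mitochondrial superoxide dismutase, averaged 113 ± 22.6 and 315 ± 41 RPKM, and Nfkbie 22 ± 2.7 and 46.7 ± 3.2 RPKM. The camera test of limma, which sets a list against the other genes, gave a Benjamini-Hochberg adjusted p of 2.3e-17 for the activation list, with an adjusted p = 0.32 with an estimated correlation. For the NF-kB list camera in limma gave a Benjamini-Hochberg adjusted p of 4.7e-17, with an adjusted p = 0.55 with an estimated correlation. Adjusted over the list alone, 16 activation genes were higher and 1, the Fc receptor gene Fcgr1, lower, while adjusted over all genes 0 were called. For NF-kB targets 8 genes were higher adjusted over the list alone and 0 over all genes, among them Bcl2a1a, whose near-identical copies make it uncertain. Markers of neutrophils, B and plasma cells, T and NK cells and dendritic cells were higher as groups in the same fit, at medians of 1.07, 0.55, 0.44 and 0.24. For these 4 lists the limma camera Benjamini-Hochberg adjusted p was 0.59, 0.55, 0.59 and 0.55 with an estimated correlation, and 0.29, 0.095, 0.45 and 0.15 without OX40 Fc replicate 1.

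Genes of co-stimulatory and checkpoint molecules were higher as a group, with a median log2 fold change of 0.54 over 22 members. Cd80, a CD28 ligand, averaged 5.78 ± 0.323 RPKM with IgG and 22.3 ± 2.48 RPKM with OX40 Fc (SD, n = 2 in each group). Cd40 averaged 28.8 ± 2.85 and 81.9 ± 22.6 RPKM, Icosl, the ICOS ligand gene, 2.17 ± 0.153 and 6.13 ± 1.1 RPKM, and Tnfsf9, the 4-1BB ligand gene, 10.7 ± 0.409 and 24.3 ± 2.58 RPKM. Havcr2, the inhibitory receptor TIM-3, averaged 11.1 ± 1.88 and 3.93 ± 1.02 RPKM. Adjusted over the list alone 9 genes were higher and 1, Havcr2, lower, and over all genes 0. In limma's camera the Benjamini-Hochberg adjusted p was 5.5e-05, with an adjusted p = 0.55 with an estimated correlation, and it was 0.095 without OX40 Fc replicate 1. Dendritic cell, B and plasma cell and T and NK cell markers were higher as groups in the same fit, at medians of 0.24, 0.55 and 0.44, with limma camera Benjamini-Hochberg adjusted p of 0.55, 0.55 and 0.59 with an estimated correlation and 0.15, 0.095 and 0.45 without OX40 Fc replicate 1.

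Transcripts of the OX40 ligand and its receptor were both measured. Tnfsf4, the OX40 ligand gene on chromosome 1 from 161395409 to 161418410, averaged 6.27 ± 0.663 RPKM with IgG and 12.2 ± 2.22 RPKM with OX40 Fc, and was higher in both OX40 Fc libraries. Its log2 fold change was 0.85 (SE 0.22), with a limma Benjamini-Hochberg adjusted p of 0.46 over all genes and 0.036 adjusted over the list alone. Tnfrsf4, the OX40 receptor gene on chromosome 4 from 156013843 to 156016612, stood at 3.79 and 3.83 RPKM in the IgG libraries and at 9.20 and 3.26 RPKM in OX40 Fc replicates 1 and 2. Its log2 fold change was 0.46 (SE 0.44, limma Benjamini-Hochberg adjusted p = 0.78), -0.17 without OX40 Fc replicate 1 and 0.81 with the length trend removed.

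Chemokine genes went in both directions. Ccl4, encoding a leukocyte attractant, averaged 80.3 ± 2.61 RPKM with IgG and 572 ± 496 RPKM with OX40 Fc, and Ccl22, a ligand of CCR4, 152 ± 34.1 and 510 ± 156 RPKM. The platelet chemokine genes Pf4 and Ppbp averaged 1670 ± 1260 and 47 ± 30.6 RPKM with IgG, against 160 ± 80.9 and 4.08 ± 0.472 RPKM with OX40 Fc. Over 22 members the median log2 fold change was 0.13, and against the IgG mean it was 0.79 in OX40 Fc replicate 1 and -0.18 in replicate 2, the library in which short genes were low. With the length trend removed the median was 0.57, and the median gene length of the list was 1466.5 bases. Adjusted over the list alone 6 genes were higher and 2 lower, and over all genes 0. The camera test of limma gave a Benjamini-Hochberg adjusted p of 0.02, and an adjusted p = 0.59 with an estimated correlation; it was 0.39 without OX40 Fc replicate 1, 0.13 without IgG replicate 2 and 0.11 with the replicate block.

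Genes of macrophage maturation were lower as a group with OX40 Fc. Of 34 members tested, 24 lay lower in both OX40 Fc libraries than in both IgG libraries, with a median log2 fold change of -1, or -0.62 after quantile normalization. Trem2, a lipid-sensing receptor of tissue macrophages, averaged 59.6 ± 26.9 RPKM with IgG and 11 ± 3.02 RPKM with OX40 Fc, and Mmp12, macrophage elastase, 141 ± 26.6 and 42 ± 13.9 RPKM. Cd14, the lipopolysaccharide co-receptor, went the other way at 124 ± 13 and 429 ± 121 RPKM. Adjusted over the list alone 3 genes (Apoe, Trem2 and Mmp12) were lower and 1, Cd14, higher, and over all genes 0. In limma's camera the Benjamini-Hochberg adjusted p was 1.4e-09, with an adjusted p = 0.55 with an estimated correlation. Kupffer cell markers, 6 of them members of this list too, were also lower as a group (median -0.58), with C1qb at 264 ± 195 RPKM with IgG and 43.9 ± 20.1 RPKM with OX40 Fc, while Adgre1, in both lists, averaged 301 ± 25.3 and 299 ± 56.8 RPKM. For the Kupffer cell list the limma camera Benjamini-Hochberg adjusted p was 0.0021, with an adjusted p = 0.59 with an estimated correlation, 0.085 without OX40 Fc replicate 2, and 0.14 with that library left out and the length trend removed.

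Lists of lysosomal, lipid and respiratory genes were lower as groups. Lysosome and phagocytosis genes had a median log2 fold change of -0.4 (-0.19 after quantile normalization) over 41 members, 21 of them lower in both OX40 Fc libraries, with Ctsl, encoding cathepsin L, at 1110 ± 178 RPKM with IgG and 496 ± 120 RPKM with OX40 Fc. Fatty acid and lipid handling genes had a median of -0.2 over 38 members. Cd36, a fatty acid uptake receptor, averaged 848 ± 285 and 201 ± 33.2 RPKM, and Cd36, Pparg and Apoe were lower adjusted over the list alone, with 0 genes over all. Oxidative phosphorylation genes had a median of -0.9 over 43 members, 30 of them lower in both OX40 Fc libraries, with Ndufa8 of respiratory complex I at 156 ± 28.9 and 86.4 ± 30.5 RPKM. That median was -0.2 in OX40 Fc replicate 1 and -1.47 in OX40 Fc replicate 2, the library in which short genes were low, and the list's median gene length was 1908 bases. With the length trend removed the log2 fold change of Ndufa8 was -0.4 in place of -0.88. The list median was then -0.68 and the list stayed called (limma camera Benjamini-Hochberg adjusted p = 1.1e-08). That correction fitted a single curve per library to all genes. The length slope of OX40 Fc replicate 2 was 0.15, 0.35 and 0.48 in genes of low, middle and high expression. The call under the correction therefore does not exclude a remaining length trend. Adjusted over the list alone and over all genes, 0 lysosomal and 0 respiratory genes were called. By limma's camera with Benjamini-Hochberg adjustment the adjusted p was 2.1e-06 for the lysosomal list, 0.033 for the lipid list and 8.9e-09 for the respiratory list, against an adjusted p of 0.59, 0.62 and 0.59 with an estimated correlation. Without OX40 Fc replicate 1 the camera p adjusted in limma by Benjamini-Hochberg was 0.11 for the lysosomal and 0.87 for the lipid list, which also stood at 0.055 without IgG replicate 1, 0.077 with the replicate block and 0.092 after quantile normalization. Hepatocyte and Kupffer cell markers were lower as groups in the same fit, at medians of -0.95 and -0.58 and a limma camera Benjamini-Hochberg adjusted p of 0.55 and 0.59 with an estimated correlation; whether such cells contribute to these lists was not tested.

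Lists of Fc receptor and MHC class II presentation genes were lower as groups, and the MHC class I list did not pass. Fc receptor genes had a median log2 fold change of -0.65 over 7 members, and Fcgr1, the high-affinity IgG receptor, averaged 94.4 ± 25.6 RPKM with IgG and 27.5 ± 4.81 RPKM with OX40 Fc. Fcgr1 and Fcgr4 were lower adjusted over the list alone, and 0 genes over all. MHC class II presentation genes had a median of -0.26 over 10 members. Lgmn, a lysosomal protease, at 501 ± 71.8 and 175 ± 30.3 RPKM was the 1 gene lower adjusted over the list alone, with 0 over all. The log2 fold change was -1.52 for Lgmn and -1.12 for the protease gene Ctss. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had -0.27, -0.18, -0.25 and -0.27, and none of these lay lower in both OX40 Fc libraries. MHC class I presentation genes had a median of 0.04 over 21 members, with 0 called either way. Kupffer cell markers were lower, and B and plasma cell and dendritic cell markers higher, as groups in the same fit. Each of those marker calls was lost with an estimated correlation, and whether such cells contribute here was not tested. In limma's camera the Benjamini-Hochberg adjusted p was 0.02 for the Fc receptor and class II lists, against an adjusted p of 0.55 and 0.59 with an estimated correlation, and it was 0.26 for class I. Both calls ended when the length trend was removed, with medians of -0.48 and -0.06 and limma camera Benjamini-Hochberg adjusted p of 0.12 and 0.22. Without OX40 Fc replicate 1 they stood at 0.12 and 0.095, after quantile normalization at 0.058 and 0.14, and class II also at 0.15 without OX40 Fc replicate 2, 0.34 without IgG replicate 1 and 0.16 without a filter, while class I stood at 0.026 without OX40 Fc replicate 2 (limma, Benjamini-Hochberg).

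Interferon-stimulated and cell cycle genes showed small group differences. Markers of T and NK cells and of B and plasma cells were higher as groups in the same fit, calls that were lost with an estimated correlation. Whether such cells contribute to the interferon-stimulated and cell cycle lists was not tested. Interferon-stimulated genes had a median log2 fold change of 0.13 over 51 members, with Gbp5, a guanylate-binding protein gene, at 1.97 ± 0.953 RPKM with IgG and 8.72 ± 0.516 RPKM with OX40 Fc. Cell cycle genes had a median of 0.11 over 25 members, with Rrm2, a ribonucleotide reductase subunit gene, at 0.949 ± 0.0219 and 2.73 ± 0.234 RPKM. In both lists 0 genes were called adjusted over the list alone and 0 over all genes. By limma's camera with Benjamini-Hochberg adjustment the adjusted p was 0.012 and 0.02, against an adjusted p of 0.62 and 0.55 with an estimated correlation. Without OX40 Fc replicate 1 these were 0.85 and 0.17, the interferon list stood at 0.053 without IgG replicate 1, and the cell cycle list at 0.73 with a filter of 5 RPKM, which Rrm2 does not reach (limma, Benjamini-Hochberg).

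Other lists did not pass as groups, although single members did when adjusted over the list alone. Of 23 genes of alternative, M2-type activation, Ccl17 and Ccl22 were higher adjusted over the list alone and Clec10a, Pparg, Cd36 and Folr2 lower, with 0 over all genes. Clec10a, a galactose-binding lectin gene, averaged 3.14 ± 0.476 RPKM with IgG and 0.347 ± 0.103 RPKM with OX40 Fc. Of 38 genes of chemokine receptors and migration, 7 were higher and 5 lower adjusted over the list alone and 0 over all, with Ccrl2, a chemerin-binding receptor gene, at 14.7 ± 3.15 and 73.9 ± 24.9 RPKM. Of 17 fibrosis and matrix genes, Inhba, encoding an activin subunit, was higher and Igf1 and Lgals3 lower adjusted over the list alone, with 0 over all. Inhba averaged 1.7 ± 0.373 and 35.9 ± 30.5 RPKM. Of 21 classical monocyte genes 3 were higher, among them Hp, encoding haptoglobin, at 22.7 ± 7.65 and 114 ± 1.57 RPKM, and 1 lower adjusted over the list alone, with 0 over all. Of 15 non-classical monocyte genes 1, Cd36, was lower adjusted over the list alone, with 0 over all. Glycolysis, cholesterol synthesis and uptake, endoplasmic reticulum stress, heat shock, NRF2 oxidative stress and hypoxia genes had 0 calls adjusted over the list alone and 0 over all, at medians of 0.00, 0.11, 0.07, -0.06, -0.27 and 0.15. The limma camera Benjamini-Hochberg adjusted p was 0.21 for the M2-type list, 0.26 for migration, 0.76 for fibrosis, 0.76 and 0.73 for the monocyte lists and 0.096 to 0.92 for the last 6. Of these, the NRF2 list alone passed with 1 library left out, at a limma camera Benjamini-Hochberg adjusted p of 0.029 without IgG replicate 2. The median, mean and camera direction differed in sign for classical monocyte genes (median -0.22, mean 0.08, higher), non-classical monocyte genes (median -0.05, mean -0.11, higher) and heat shock genes (median -0.06, mean -0.02, higher), while fry gave fibrosis genes (median 0.2) as lower.

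Markers of cell types other than monocytes also differed between the groups. Hepatocyte genes had a median log2 fold change of -0.95 over 20 members, 17 of them lower in both OX40 Fc libraries, and Alb, the albumin gene, averaged 27 ± 8.16 RPKM with IgG and 9.64 ± 0.41 RPKM with OX40 Fc. Kupffer cell genes had a median of -0.58 over 17 members, with Folr2, a folate receptor gene, at 44.8 ± 35.2 and 2.84 ± 2.34 RPKM, and Marco, a scavenger receptor gene, at 22.1 ± 5.57 and 73.7 ± 5.09 RPKM. The Kupffer cell marker Clec4f was too low to be tested, at 0.768 and 0.223 RPKM with IgG and 0.125 and 0.0961 RPKM with OX40 Fc. Neutrophil genes had a median of 1.07 over 15 members, at 2.68 in OX40 Fc replicate 1 and 0.53 in OX40 Fc replicate 2. S100a8, an abundant neutrophil transcript, stood at 113 and 53.1 RPKM in the IgG libraries and at 1040 and 13.2 RPKM in OX40 Fc replicates 1 and 2. B and plasma cell genes had a median of 0.55 over 10 members, or 0.84 with the length trend removed, with Cd79a, a B cell receptor component, at 1.01 ± 0.632 and 4.13 ± 0.143 RPKM. T and NK cell genes had a median of 0.44 over 19 members, with Gzmb, encoding granzyme B, at 0.672 ± 0.735 and 5.57 ± 0.337 RPKM. Dendritic cell genes had a median of 0.24 over 17 members.

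In limma's camera with Benjamini-Hochberg adjustment the adjusted p was 1.2e-11 for hepatocyte, 0.0021 for Kupffer cell, 9.3e-05 for neutrophil, 0.012 for B and plasma cell, 0.0027 for T and NK cell and 0.012 for dendritic cell genes. With an estimated correlation the adjusted p was 0.55 for the hepatocyte, B and plasma cell and dendritic cell lists and 0.59 for the Kupffer cell, neutrophil and T and NK cell lists. Adjusted over the list alone, 7 hepatocyte genes were lower, 5 Kupffer cell genes lower and 1 higher, 2 neutrophil genes (Lcn2 and Mmp9) higher, 5 B and plasma cell genes higher and 1 lower, 1 T and NK cell gene higher and 0 dendritic cell genes called, with 0 over all genes in each list. Without OX40 Fc replicate 1 the limma camera Benjamini-Hochberg adjusted p was 0.29 for neutrophil, 0.095 for B and plasma cell, 0.45 for T and NK cell and 0.15 for dendritic cell genes, and without OX40 Fc replicate 2 it was 0.085 for Kupffer cell genes. With a filter of 5 RPKM it was 0.16 for T and NK cell genes, and with the length trend removed and OX40 Fc replicate 2 left out it was 0.083 for B and plasma cell genes (limma, Benjamini-Hochberg). Endothelial and stellate cell genes (median 0.07 over 20 members) and eosinophil, basophil and mast cell genes (median 0.11 over 5 members) did not pass, at limma camera Benjamini-Hochberg adjusted p of 0.61 and 0.58. Of these, Ccr3 was lower and Hdc higher adjusted over the list alone, with 0 over all genes, and 0 endothelial and stellate genes were called. Only 4 erythroid and platelet genes were tested, too few for a list test; their median was -1.61, and Pf4 and Ppbp were lower adjusted over the list alone, with 0 over all.

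**Figure D3:**
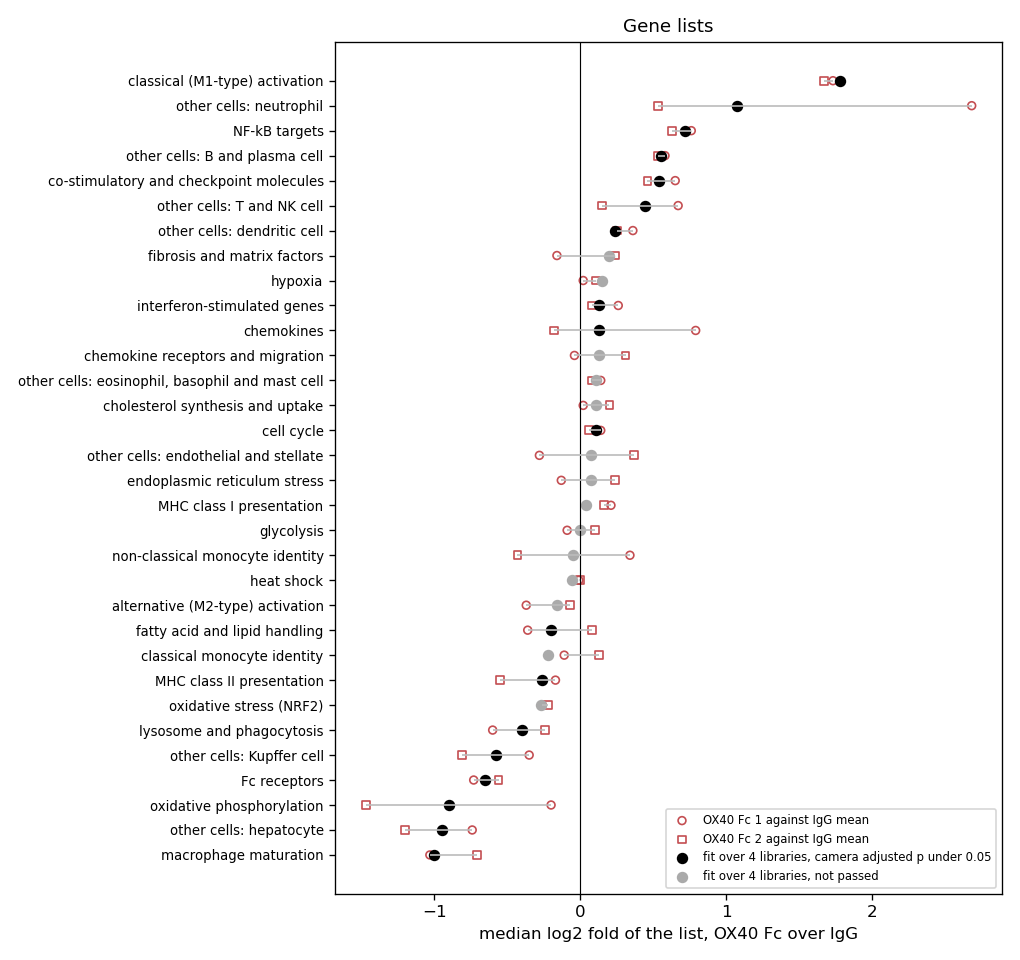
Median log2 fold change, OX40 Fc over IgG, of each of the 32 tested gene lists: filled points show the fit over 4 libraries, black where the camera adjusted p lay under 0.05 and grey where not, and open symbols show each OX40 Fc library against the IgG mean. M1-type activation lies at 1.78 with both open symbols near it, while oxidative phosphorylation (-0.2 and -1.47) and neutrophil genes (2.68 and 0.53) lie apart between the OX40 Fc libraries.

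Across the 32 lists tested, limma's camera with a preset correlation of 0.01 called 10 higher and 8 lower at a Benjamini-Hochberg adjusted p under 0.05, or 12 and 5 after quantile normalization. With an estimated correlation 0 lists were called, and the smallest Benjamini-Hochberg adjusted p in limma was 0.32. The fry test of limma, which asks whether a list's genes move on balance in 1 direction, called 0 lists, with a smallest Benjamini-Hochberg adjusted p of 0.067, and its mixed form, which counts changes in either direction, called 7. Of the 18 lists called, 6 were also called in the same direction without OX40 Fc replicate 1 and 16 without OX40 Fc replicate 2. In all 15 alternative fits, 5 lists were called: M1-type activation and NF-kB targets higher, and macrophage maturation, oxidative phosphorylation and hepatocyte genes lower. These fits drew on the same 4 libraries and used the preset correlation, so they are not independent evidence. For oxidative phosphorylation a remaining length trend was not excluded.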

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

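The alternatives with a length correction or limma-voom were chosen after the results were seen; the others were fixed before the data were examined. The count of genes passing in limma stayed at 0 higher and 0 lower without a filter, with a filter of 5 RPKM, with a pseudocount of 0.1, with trimmed mean scaling, quantile normalization, no variance trend and limma-voom. At an adjusted p under 0.1 it was 7 higher and 0 lower. It was 17 higher and 1 lower with the length correction, and 71 and 34 with the length correction and OX40 Fc replicate 2 left out. With 1 library left out in turn the counts ranged from 0 to 465 higher and from 0 to 1258 lower: both fits without an IgG library gave 0 and 0, the fit without OX40 Fc replicate 2 gave 120 and 93, and that without OX40 Fc replicate 1 gave 465 and 1258, on fewer libraries. Lists called ranged from 2 to 11 higher and 4 to 9 lower over the same 4 fits. Lists called lower numbered 5 under quantile normalization, and 0 lists were called higher or lower with an estimated correlation or with fry's directional test. Apart from the construction of the fits with fewer libraries, the cause was not tested.

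The replicate numbers are shared by the groups, but the labels tie them to no animal or day, and the correlation of same-numbered deviations was 0.22 over only 2 pairs. With the replicate block limma gave 0 higher and 0 lower genes, and 9 lists higher and 7 lower, with chemokines (adjusted p 0.11, limma, Benjamini-Hochberg) and lipid handling (0.077) no longer called. With the length correction and the replicate block it gave 33 genes higher and 5 lower.

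Some values that did not pass changed direction, with neither value passing, and the cause was not tested. With 1 library left out in turn, the log2 fold change of Tnfrsf4 ranged from -0.17 to 1.08. List medians ranged from -0.07 to 0.40 for migration, -0.43 to 0.51 for non-classical monocyte, -0.17 to 0.10 for glycolysis, -0.13 to 0.24 for endoplasmic reticulum stress, -0.10 to 0.07 for heat shock, -0.53 to 0.06 for NRF2, -0.16 to 0.30 for fibrosis, -0.28 to 0.37 for endothelial and stellate, and -0.08 to 0.33 for eosinophil, basophil and mast cell genes. With the length correction and OX40 Fc replicate 2 left out, medians were 0.01 for migration, -0.07 for classical monocyte, -0.04 for glycolysis, -0.09 for endoplasmic reticulum stress, -0.12 for fibrosis and -0.25 for endothelial and stellate genes. Non-classical monocyte genes were at -0.05 without a filter and -0.24 with a filter of 5 RPKM, heat shock genes at -0.06 with the replicate block, and NRF2 genes at 0.00 after quantile normalization; for several of these the test's direction turned and not the median. Lists that ceased to pass were Fc receptors (limma camera Benjamini-Hochberg adjusted p 0.058), MHC class II (0.14) and lipid handling (0.092) after quantile normalization, class II without a filter (0.16), and cell cycle (0.73) and T and NK cell genes (0.16) with the filter of 5 RPKM, under which B and plasma cell genes were too few. With the length correction and OX40 Fc replicate 2 left out, class II (0.14), B and plasma cell (0.083) and Kupffer cell genes (0.14) ceased to pass. Hypoxia genes came to pass after quantile normalization (limma camera Benjamini-Hochberg adjusted p 0.028), with the filter of 5 RPKM (0.03) and with the length correction (0.024). Class I genes came to pass after quantile normalization (0.014), and eosinophil, basophil and mast cell genes without a filter (0.03). Of the alternative values of single genes and list tests, counts of calls left aside, 1400 kept their direction and side of the threshold, 160 came to pass, 33 ceased to pass and 24 reversed. A count-model test and alternatives that the plan kept for deposited counts were not run, since the deposited values are RPKM. The implied reads were tested only with limma-voom, which was added after the data were seen. Depth limits short and low genes: Il12a rested on 1 and 14 reads with IgG.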

Other observations

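The tests of OX40 Fc replicate 1 along length, of the inflammatory genes against the length trend, of neutrophils in each library and of other constituents were chosen after the results were seen; the other tests were set before their results but after the patterns were noticed.

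Immunoglobulin transcripts were scarce with IgG and more frequent with OX40 Fc. Over 111 immunoglobulin genes the implied reads summed to 318 and 1683 in the IgG libraries and to 5192 and 7075 in OX40 Fc replicates 1 and 2, or 13.7, 66.3, 228.7 and 209.9 RPM on each library's scale. Ighg2b, the IgG2b constant region gene, was listed at 0 in both IgG libraries and at 6.73 and 6.14 RPKM with OX40 Fc, and Igkc, the kappa constant region gene, stood at 3.81, 38, 101 and 103 RPKM. Among monocyte markers, Adgre1, which encodes F4/80, stood at 318, 283, 339 and 259 RPKM and Csf1r at 132, 171, 103 and 172 RPKM. Ccr2, the receptor that marks monocytes leaving the bone marrow, stayed at 0.361 to 0.565 RPKM in all 4 libraries. Mitochondrial ribosomal RNA mt-Rnr2 stood at 27000, 13100 and 20700 RPKM in the first 3 libraries and at 3520 RPKM in OX40 Fc replicate 2.

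Shorter genes were lower in OX40 Fc replicate 2, at a slope of 0.26 per doubling of length. A response to OX40 Fc shared by both libraries is argued against by the slope of -0.03 in OX40 Fc replicate 1. Ribosomal protein, respiratory chain, mitochondrial and histone genes do not account for it, since the slope was 0.23 without these 372 genes. A length-dependent yield of that library is a candidate explanation: the slope was positive in genes of low, middle and high expression, at 0.15, 0.35 and 0.48. Whether the RNA or the library preparation differed was not tested.

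The higher immunoglobulin transcripts may come from plasma cells among the sorted cells. Of Jchain and Mzb1, plasma cell genes outside the immunoglobulin loci, 2 of 2 were higher in both OX40 Fc libraries. Jchain stood at 0.0171 and 1.81 RPKM with IgG against 4.08 and 6.05 RPKM with OX40 Fc. Both genes belong to the B and plasma cell list and are not evidence separate from it. Counting error from few reads is argued against by 5192 reads in the lower OX40 Fc library against at most 1683 with IgG. This does not cover variation between samples, since the IgG libraries themselves held 318 and 1683 reads. A stricter bound on the ratio of IgG to OX40 Fc reads, set after the pattern was noticed but before its result, was not met. That bound concerned the size of the difference and not the number of reads. The sort took cells with intermediate CD11b and low F4/80, and its purity was not tested. Which cells carried the reads stays open, as does a response to OX40 Fc, which was not tested.

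The 12 named higher genes, several of them inflammatory, were higher in both OX40 Fc libraries, and the length trend of OX40 Fc replicate 2 argues the other way: fitted over all genes, it shifted these 12 by a median log2 of -0.44 against the IgG mean in that library, where their median log2 fold was 3.31. Neutrophils among the sorted cells were tested, after the pattern was noticed, by S100a8 and S100a9 being higher in both OX40 Fc libraries. Of these 2 genes 0 were, which decided neither way because the group mean was higher. Taken per library after length correction, their mean log2 fold change was 3.78 in OX40 Fc replicate 1, where neutrophils may contribute. In OX40 Fc replicate 2 it was -1.19, which argues against added neutrophils only if the correction removed the length trend of these genes. Both are short and abundant, and the length slope of that library was 0.48 in highly expressed genes against 0.26 over all. Of the 15 neutrophil list genes, 9 were higher in both OX40 Fc libraries, against 2051 of all 10885 genes tested. The 9 include Lcn2, which is also 1 of the 12 named genes. The neutrophil list median in OX40 Fc replicate 2, without length correction, was 0.53. Ly6g, also on that list, stood at 0.137 and 0.0417 RPKM with IgG and at 0.187 and 0 RPKM in OX40 Fc replicates 1 and 2. The list members Mpo, Cxcr2 and Trem1 were higher in both OX40 Fc libraries, at no more than 1.78 RPKM. These genes fell below the filter and were not tested. A response to OX40 Fc binding and another constituent of the added protein, such as endotoxin, cannot be told apart, because 0 libraries had the protein without contact to the OX40 ligand. A response to OX40 Fc therefore remains 1 of the open explanations.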
